A study of Homo sapiens with 12 samples.

How the data were processed

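RNA from telomerase-immortalised human mammary epithelial cells was hybridised as biotinylated cRNA to Illumina BeadChips, per the labels' protocols. The 12 arrays form 6 groups of 2, wild type or RELA S276A, each untreated, given EGF at 100 ng/mL or given IL-1β at 10 ng/mL for 4 h. For the intensity values deposited by the authors, GenomeStudio 2011.1 is named as software per the submitters' processing notes, and its steps and settings are not given in the sources used here. The deposited intensities are linear, from −25.2 to 27859.96, and 28.8% of them lie below 0, as happens when background has been subtracted. Their median is 8.79 to 8.82 and their 75th percentile 68.22 in every array, as happens after quantile normalisation between arrays. Replicates were not pooled. No detection p-values, raw scans or bead-level values were used here.

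Intensities below 0 were set to 0, 16 was added, and the sums were put on a log2 scale. No further normalisation was applied. A probe was tested if its intensity exceeded the median of all values, 8.81, in at least 2 of the 12 arrays, which kept 30728 of 47315 probes (64.9%). The filter did not look at group. Of all probes 30109 carry 1 gene symbol, 8 carry several and 17198 carry none or are not listed. Symbols were compared with a RefSeq gene table, where 30070 of 30109 named probes matched, and 0 symbols needed updating. The 20799 tested probes with 1 symbol cover 15028 genes, 4283 of them with more than 1 tested probe. Each gene is represented by its probe with the highest mean over the 12 arrays. Where another probe of a named gene moves the other way, the report says so. The background limit, 14.23 intensity units or 4.92 on the log2 scale, mirrors percentile 2 of the values below 0, taken as noise around 0. Fold changes from or to a level below this limit are given as "at least", computed on intensities without the added 16, so they can exceed the fitted log2 change, and fitted log2 values that involve such a level are not exact.

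Each probe was fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group and 6 residual degrees of freedom. Variances were moderated with an intensity trend, which gave 16.46 prior degrees of freedom. The 9 planned comparisons were EGF and IL-1β against untreated in each genotype, the genotype difference in each response, the genotype effect in untreated cells and averaged over treatments, and IL-1β against EGF in wild type. All p-values are from limma moderated statistics adjusted by Benjamini-Hochberg over the tested probes, with a threshold of 0.05. Those for lists are from camera in limma. Standard errors come from the fit, which pools variance over groups and probes. The choices were fixed before the data were examined. The genotype effects under EGF and under IL-1β, and an overlap with the untreated arrays split between the responses, were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in python 3.11.15, and random draws used seed 20.

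Genes were named by a rule. For each comparison it took the 10 largest rises and 10 largest falls past the threshold whose arrays do not overlap, and for interactions past the threshold alone. It added up to 4 members past the threshold from each gene list. RELA, NFKBIA, TNFAIP3, CXCL8, IL6, ICAM1, EGR1, DUSP6, FOSL1 and IL1B were always followed. The text prints a part of the genes so named.

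The 25 gene lists, written from general knowledge, were NF-κB targets, chemokines and cytokines, antimicrobial and acute phase genes, EGFR-ERK early and feedback genes, EGF family ligands, and matrix proteases, integrins and migration genes. Also used were interferon-stimulated genes, antigen presentation, G1/S and DNA replication, G2/M and mitosis, p53 targets, cholesterol synthesis, glycolysis and hypoxia, unfolded protein and integrated stress response, NRF2 antioxidant targets, TGF-β and SMAD targets, ribosome biogenesis and MYC targets, pathway components, and housekeeping controls. Marker lists covered squamous, basal, luminal, fibroblast, immune and endothelial cells. Lists share genes, and 24 of the 42 NF-κB targets listed, measured or not, are also in another list. Each was tested with camera over 1 probe per gene, with its preset correlation between genes, adjusted over 225 tests, and again with a correlation estimated per list. Of the 6 endothelial markers 0 lay above the background limit on average.

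The labels number replicates, and array positions split the chip into upper and lower ends with 1 array of every group in each. Residuals of arrays with the same replicate number correlated at a median r of −0.0037 over 15 pairs of groups (−0.11 to 0.12), and those at the same end at 0.016 (−0.019 to 0.12). Arrays were therefore treated as unpaired. Alternatives tried were no probe filter, a filter at the 75th percentile, quantile normalisation or median centring again, offsets of 1 and 64, no intensity trend, only the groups compared, a replicate or chip-end block, array weights, each array left out in turn, and other probes of a gene.

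The steps were tested on simulated data with known changes. These were planted only in probes with a mean level above the background limit, so the recovery rates do not cover probes near or below it. For EGF in wild type they recovered 43.3% of 1.5-fold, 89.6% of 2-fold and 100% of 4-fold changes, with 13 false calls. For the genotype difference in the EGF response they recovered 10.4%, 58.2% and 98.5%, with 5 false calls. For IL-1β in wild type, simulated arrays with no change gave 2 calls among 30728 probes. Among 21 simulated lists of 30 genes, camera found the list shifted by 0.5 (adjusted p = 5.55e-15) and called 0 others. Simulated probes were drawn independently of each other, so this does not test lists of correlated genes.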

Results

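The data are 12 BeadChip arrays of telomerase-immortalised human mammary epithelial cells, in 6 groups of n = 2. Cells carried either unedited RELA, called wild type here, or RELA edited so that a serine that can be phosphorylated reads alanine (S276A). After a night without EGF-containing supplements, each genotype was left untreated, or given EGF at 100 ng/mL or IL-1β at 10 ng/mL, for 4 h. Of 47315 probes, 30728 passed the signal filter, and these probes cover 15028 genes by name. In every array 42.5% of probes lay above the background limit of 14.23 intensity units, which is 4.92 on the log2 scale used below. Replicate arrays correlated at r = 0.979 to 0.986 across tested probes, and probes are not independent replicates. The first principal component held 26.5% of the variance and the next component 20.5%. Having 2 arrays per group limits the precision of every estimate. The labels do not say whether replicates are separate cultures, so p measures the spread between these arrays, which may be technical only.

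RELA encodes the p65 subunit of NF-κB and is the edited gene. Its transcript lay above the background limit in all 12 arrays. In wild type its log2 level was 5.93 ± 0.18 untreated, 6.09 ± 0.10 with EGF and 5.99 ± 0.28 with IL-1β (mean ± SD, n = 2). In S276A it was 5.79 ± 0.012, 6.05 ± 0.23 and 6.25 ± 0.31 in the same order. Averaged over treatments, the genotypes differed by 0.027 ± 0.15 (log2 difference ± standard error, limma adjusted p = 0.941). The edit changes an amino acid, so a transcript probe cannot check that it is present. Each genotype stands for 1 line by label, so genotype is confounded with clone and culture history throughout.

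EGF raised chemokine genes and genes for making ribosomes in wild-type cells. CXCL8, a neutrophil attractant, rose by 3.56 ± 0.27 (log2 change ± standard error, n = 2 per group here and below, adjusted p = 4.06e-09), from a mean of 6.09 untreated. CXCL1 rose by 2.50 ± 0.25, and the cytokine IL1B by 2.10 ± 0.13. The ligands TGFA and NRG1, which feed back on EGF-family receptors, rose by 1.67 ± 0.15 and 2.32 ± 0.13, although another probe for NRG1 moved the other way. RRS1 and DDX21, which act in ribosome assembly, rose by 2.60 ± 0.19 and 1.78 ± 0.12. PHLDA2, a growth-restraining imprinted gene, rose by 2.90 ± 0.28, the MAP kinase phosphatase DUSP4 by 2.34 ± 0.19, and the sterol enzyme HMGCS1 by 1.93 ± 0.12. The A20 gene TNFAIP3, a brake on NF-κB, rose by 1.45 ± 0.15. FBXO32, a ubiquitin ligase subunit active in quiescent cells, fell by 4.30 ± 0.12 (adjusted p = 1.09e-16). CYP1B1 and CYP1A1, which oxidise aromatic compounds, fell by 3.99 ± 0.19 (to below the background limit, at least 25.4-fold in intensity without the added 16) and 3.84 ± 0.26. The scavenging chemokine receptor ACKR3 fell by 4.00 ± 0.23 to below the background limit, a fall of at least 22.3-fold. The early transcription factor EGR1 fell by 3.11 ± 0.24 and the repressor BCL6 by 3.07 ± 0.18. The death ligand TNFSF10 fell by a fitted 2.78 ± 0.33, not exact because 1 of 2 EGF arrays lay below the limit. NFKBIA, which encodes the NF-κB inhibitor, changed by 0.36 (adjusted p = 0.109), IL6 by 0.48 (0.418) and ICAM1 by −0.056 (0.959), so none of these passed the test. In total 3014 probes passed, naming 1031 genes that rose and 1062 that fell, of which 314 and 320 moved at least 2-fold. The count was 1772 without an intensity trend in the variance and 1030 when only these 4 arrays were fitted.

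Ribosome biogenesis genes rose as a set with EGF, with 19 of 26 up (21 adjusted over the list alone) and a median of 0.89 (camera adjusted p = 4.66e-16, and adjusted p = 0.0428 with an estimated correlation). Among EGFR-ERK early and feedback genes, 16 rose and 4 fell of 38 (21 and 5 adjusted over the list alone, camera adjusted p = 7.15e-07, 0.0258 with an estimated correlation). Chemokines and cytokines showed 10 up and 2 down of 30 (10 and 2 over the list alone, 0.000806, 0.0457 estimated). NF-κB targets showed 10 up and 3 down of 37 (12 and 3 over the list alone, median 0.34, camera adjusted p = 0.000325), but adjusted p = 0.134 with an estimated correlation. Cholesterol synthesis genes rose, 8 up and 1 down of 19 (10 and 1 over the list alone, 0.000209), as did matrix proteases and integrins with 7 of 21 (7 over the list alone, 0.00134), with MMP3 at 1.49 ± 0.12. These gave adjusted p = 0.138 and 0.352 with an estimated correlation. Mitotic genes fell, 10 of 35 (12 over the list alone, median −0.34, 0.000723), and p53 targets fell, 8 of 23 with 1 up (10 and 1 over the list alone, 0.00069), SESN1 at −2.28 ± 0.17 among them. Their adjusted p = 0.527 and 0.059 with an estimated correlation.

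Smaller set shifts with EGF were glycolysis genes up (8 up and 2 down of 27, adjusted p = 0.014) and unfolded protein response genes up (5 up and 2 down of 22, 0.015). NRF2 antioxidant targets fell (6 of 20, 0.0158), with HMOX1 at −1.52 ± 0.22, and EGF family ligands rose (2 of 5, 0.0292). With an estimated correlation these gave adjusted p = 0.0879, 0.119, 0.255 and 0.155. Adjusted over the list alone, their counts were 9 up and 2 down, 6 up and 3 down, 2 up and 7 down, and 2 up. The other lists did not shift in camera. Antimicrobial genes gave adjusted p = 0.415, antigen presentation 0.97, G1/S genes 0.0722, TGF-β targets 0.853, pathway components 0.355 and housekeeping controls 0.843. Interferon-stimulated genes had a median of 0.012, a mean of −0.14 and a downward test (adjusted p = 0.584). Among cell-type markers, squamous genes gave 0.315, basal 0.827, luminal 0.859, fibroblast 0.119, immune 0.893 and endothelial 0.889, and COL1A1, a fibroblast collagen, fell by 1.69 ± 0.17. Of 13 immune and 6 endothelial markers measured, 0 passed limma adjustment and 0 had an unadjusted p below 0.05.

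IL-1β raised inflammatory genes far more than EGF did in wild-type cells. CXCL8 rose by 6.12 ± 0.27 (adjusted p = 7.02e-13) and CXCL1 by 5.59 ± 0.25, both neutrophil attractants. LTB, a lymphotoxin subunit, rose by 5.04 ± 0.29 from below the background limit, at least 45.3-fold, and TNFAIP6, a hyaluronan-binding protein of inflamed tissue, by 5.56 ± 0.46. IL6 rose by 3.48 ± 0.30 (at least 15-fold, adjusted p = 7.71e-08), CCL20 by at least 19.5-fold, and the complement gene CFB by 4.43 ± 0.28. The NF-κB inhibitor genes NFKBIA and TNFAIP3 rose by 1.75 ± 0.13 and 3.5 ± 0.15, and the adhesion receptor ICAM1 by 1.60 ± 0.34 (adjusted p = 0.0102). Antiviral IFIT2 rose from below the background limit by at least 12.8-fold (fitted log2 change 3.41 ± 0.35). The T-cell attractant CXCL10 rose by a fitted 3.19 ± 0.28, not exact because 1 of 2 untreated arrays lay below the limit, and both are induced by interferon. ACKR3 fell by 2.18 ± 0.23 and the G-protein regulator RGS2 by 1.33 ± 0.15. EGR1 (−0.46), FOSL1 (0.32) and DUSP6 (−0.0048) did not pass. In total 497 probes passed, naming 228 genes that rose and 130 that fell. The count was 178 without an intensity trend, and 28 when only these 4 arrays were fitted.

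Of NF-κB targets 27 of 37 rose with IL-1β and 0 fell (29 over the list alone, median 1.51, camera adjusted p = 2.97e-53, 0.00348 with an estimated correlation, and 0 fell at unadjusted p below 0.05). Chemokines and cytokines rose, 14 of 30 (15 over the list alone, adjusted p = 1.94e-21), as did antimicrobial genes, 5 of 14 (7 over the list alone, 4.04e-10), with the protease inhibitor PI3 at 3.40 ± 0.27. Interferon-stimulated genes rose, 7 of 31 (11 over the list alone, median 0.41, 1.88e-11). EGFR-ERK genes (4 of 38, 9 up and 2 down over the list alone, 0.000236) and pathway components (6 of 35, 6 over the list alone, 0.000612) also rose. All of these held with an estimated correlation, the weakest at adjusted p = 0.0457. Proteases (4 of 21, 5 over the list alone, 0.00314), antigen presentation (3 of 15, 4 over the list alone, 0.00426), ribosome biogenesis (2 of 26, 3 over the list alone, 0.0166) and EGF family ligands (2 of 5, 3 up and 1 down over the list alone, 0.0237) rose with the preset correlation only. These gave adjusted p = 0.393, 0.0737, 0.369 and 0.148 with an estimated correlation. Cell-type markers did not shift, with adjusted p of 0.509 for squamous, 0.33 basal, 0.0908 luminal, 0.149 fibroblast, 0.644 immune and 0.749 endothelial. Nor did G1/S genes (0.97), mitotic genes (0.843), p53 targets (0.192), cholesterol (0.264), glycolysis (0.51), unfolded protein (0.305), NRF2 (0.132), TGF-β (0.794) or housekeeping genes (0.749).

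Tested directly against each other in wild type, IL-1β exceeded EGF most for TNFAIP6, by 4.58 ± 0.46, CFB by 4.24 and LTB by 3.90. The chemokine CXCL8 was 2.56 ± 0.27 higher after IL-1β and IL6 3.01 higher. Genes that EGF had lowered also stood higher after IL-1β, such as FBXO32 by 3.39 ± 0.12 and EGR1 by 2.65. EGF gave the higher level for HS3ST3A1, a heparan sulfate enzyme, at −2.32 ± 0.19, for PHLDA2 at −2.24 and for HMGCS1 at −1.34. IL1B was lower after IL-1β than after EGF, at −1.0 ± 0.13. In total 2298 probes passed (limma), 801 genes higher with IL-1β and 820 with EGF. NF-κB targets were higher with IL-1β (25 up and 1 down of 37, 27 and 1 over the list alone, camera adjusted p = 3.14e-21, 0.0154 estimated). Ribosome biogenesis genes were higher with EGF (15 of 26, 19 over the list alone, 5.36e-14, 0.0457 estimated). EGFR-ERK genes were higher with EGF by preset correlation (14 against 5 of 38, 17 and 6 over the list alone, 0.000512), with adjusted p = 0.0506 with an estimated correlation. The probe count was 347 when only these 4 arrays were fitted and 1179 without an intensity trend.

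Many of the same genes passed in the EGF and the IL-1β response of wild type, 113 rising in both and 105 falling in both, with 11 opposite. CXCL8, CXCL1, TNFAIP3 and IL1B rose with each stimulus, and ACKR3 fell with each. By probe, 300 moved in the same direction and 12 in opposite directions, where independent lists would give 15.4 up, 8.97 down and 24.4 opposite. Both responses use the same 2 untreated arrays, and simulated unchanged arrays gave a mean overlap of 0.12 and at most 1. Almost no probe passes when nothing changes, so this low overlap is built in. It does not measure what shared controls add where many probes respond. The covariance of the responses across probes was 0.071 against 0.0407 simulated, and the correlation 0.443 against 0.499. Part of the excess may come from the shared controls. With 1 untreated array given to each response, a test added after the result was seen, 98 or 81 probes moved in the same direction and 5 in opposite directions, depending on which array went where. Independent lists would then give 5.08 or 4.95, and r was 0.163 or 0.183. The overlap of 300 became 144 without a probe filter, 79 without an intensity trend and 9 when only the groups compared were fitted. Pairs with no array in common also overlapped, 221 probes for EGF in wild type with IL-1β in S276A and 289 for EGF in S276A with IL-1β in wild type. Independent lists would give 17.1 and 3.74, and 19.9 and 11, in those pairs. Opposite moves numbered 33 and 22, against 21 and 30.5 for independent lists. Across probes r was 0.18 and 0.209, and genes are not independent replicates.

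In S276A cells EGF raised PHLDA2 by 3.40 ± 0.28 (adjusted p = 7.39e-09), RRS1 by 3.06 ± 0.19 and the hyaluronan synthase HAS2 by at least 10.6-fold. The matrix protease MMP3 rose by 2.89 ± 0.12 (5.44e-13), the transcription cofactor CITED4 by 2.78 ± 0.14 and IL1B by 2.64 ± 0.13. ACKR3 (−4.13 ± 0.23), FBXO32 (−4.07 ± 0.12, adjusted p = 3.63e-16) and EGR1 (−3.71 ± 0.24) fell. The ERK-induced genes FOSL1 and DUSP6 rose by 1.66 ± 0.19 and 1.04 ± 0.17. CXCL8 did not pass, at 0.36 ± 0.27 (adjusted p = 0.498), nor did TNFAIP3 at 0.14 (0.677) or NFKBIA at −0.30 (0.167). In total 3791 probes passed, 1312 genes up and 1294 down. EGFR-ERK genes rose (23 up and 4 down of 38, 25 and 4 over the list alone, median 0.91, adjusted p = 9.94e-11, 0.0141 estimated), and ribosome biogenesis genes rose (18 of 26, 20 over the list alone, 3.7e-13, 0.0488 estimated). Mitotic genes fell, 18 of 35 (24 over the list alone, 5.78e-07), with adjusted p = 0.36 with an estimated correlation. Proteases rose (9 up and 2 down of 21, 12 and 2 over the list alone, 9.67e-05), with adjusted p = 0.269 with an estimated correlation. NF-κB targets did not shift as a set (8 up and 3 down of 37, adjusted p = 0.0786). The probe count was 2474 without an intensity trend and 1796 when only these 4 arrays were fitted.

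IL-1β in S276A cells raised CXCL8 by 7.05 ± 0.27 (at least 158-fold, adjusted p = 8.45e-14), CXCL2 by 5.17 ± 0.22 and IL6 by 4.30 ± 0.30 (at least 23.3-fold). IRF1, a transcription factor of interferon responses, rose by 3.54 ± 0.15, NFKBIA by 2.23 ± 0.13 and TNFAIP3 by 2.75. The tight junction gene CLDN1 rose by 3.12 and the phosphatase gene DUSP1 by 1.64, and the clock gene DBP fell by 1.74. ICAM1 did not pass, at 0.13 (adjusted p = 0.972), nor did FOSL1 at 0.73 (0.0534). In total 427 probes passed, 255 genes up and 52 down. NF-κB targets rose (21 of 37, 25 over the list alone, median 1.20, camera adjusted p = 1.09e-42, 0.00348 estimated), as did EGFR-ERK genes (14 of 38, 21 over the list alone, 3.33e-18, 0.00348 estimated). EGF family ligands rose (3 of 5, 4 over the list alone, 6.34e-08, 0.0258 estimated). Chemokines (10 of 30, 14 over the list alone, adjusted p = 4.04e-18) and antimicrobial genes (6 of 14, 7 over the list alone, 6.06e-09) rose as well. Interferon-stimulated genes did not shift (0 of 31 in limma, 1 up and 2 down at unadjusted p below 0.05, adjusted p = 0.843). The probe count was 161 without an intensity trend and 80 when only these 4 arrays were fitted.

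Most wild-type responses kept their sign in S276A. Of the probes passing with EGF in wild type, 95.9% had the same sign in S276A, and 2063 passed in both with 1 in opposite directions. For IL-1β, 92.4% had the same sign, and 208 passed in both. Over all tested probes, which include many near background, the responses correlated at r = 0.55 for EGF and 0.272 for IL-1β, with slopes of 0.593 and 0.265. Genes are not independent replicates. With a filter at the 75th percentile of signal r became 0.81 and 0.585, and with an offset of 1 on the intensities it became 0.215 and 0.0747.

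**Figure D1:**
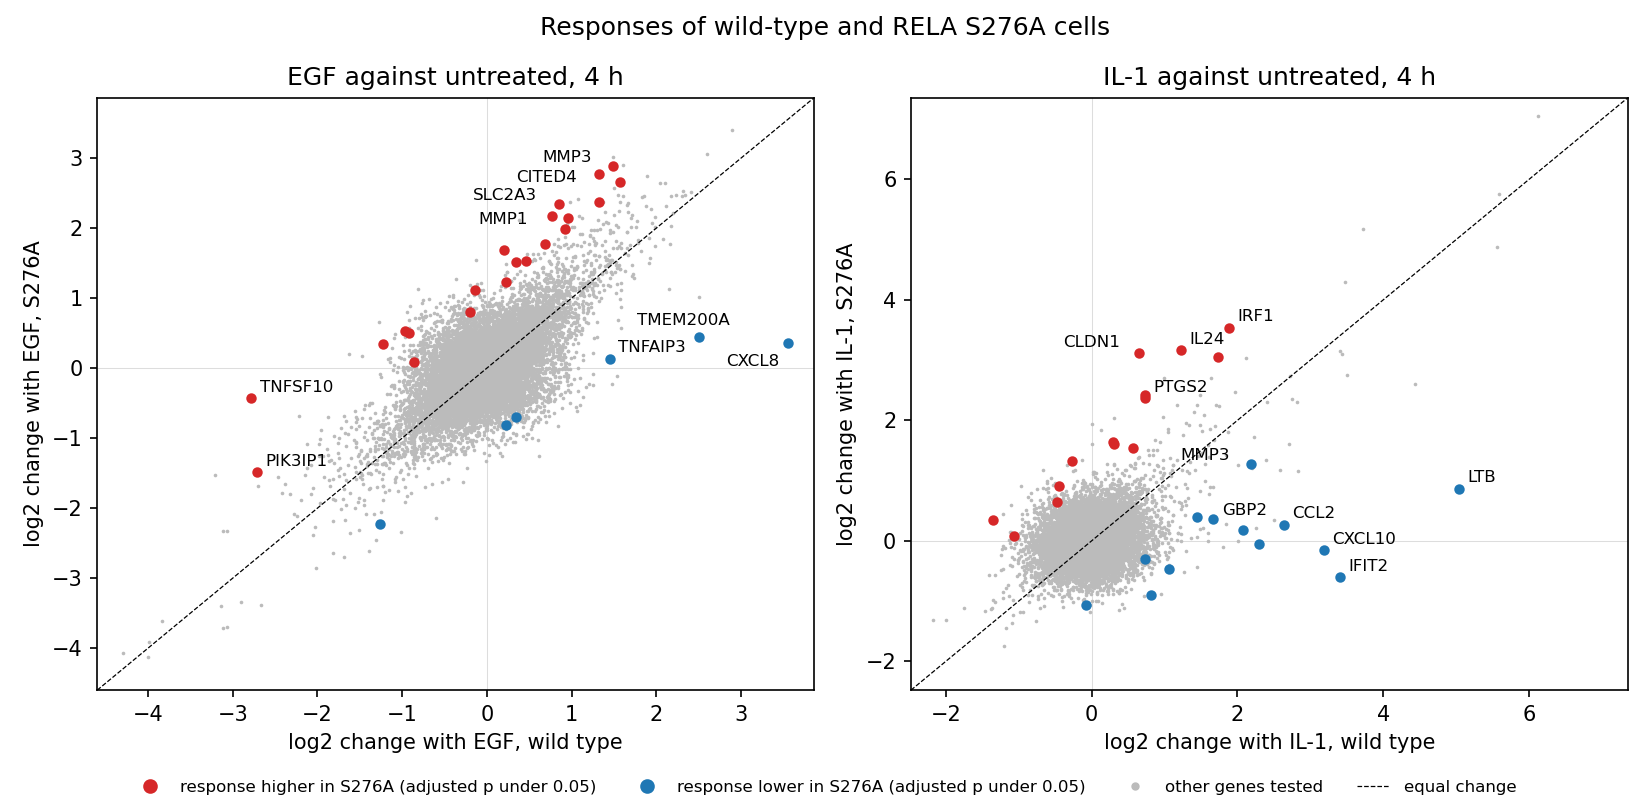
Log2 response to EGF and to IL-1β in wild type (horizontal) against S276A (vertical), 1 point per gene, each response from 2 treated and 2 untreated arrays. Marked points differ between genotypes past adjusted p of 0.05, such as CXCL8 with EGF at −3.21.

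The direct test of the genotype difference in the EGF response found genes that responded less in S276A. CXCL8 changed by 3.56 in wild type and 0.36 in S276A, a fitted difference of −3.21 ± 0.38 (adjusted p = 0.000697). In S276A both its untreated level of 4.10 and its EGF level of 4.46 lay below the background limit, so no response was measured there and the difference is not exact. TNFAIP3 differed by −1.31 ± 0.21 (0.0125) and TMEM200A, a membrane protein gene, by −2.07 ± 0.41 (0.0458), also with both S276A levels below the limit. Matrix protease genes gained more in S276A, MMP3 by 1.40 ± 0.18 (0.000931), MMP1 by 1.41 ± 0.24 (0.0136) and MMP10 by 1.49. So did the ERK phosphatase gene DUSP5 by 1.25 ± 0.22, the receptor inhibitor SPRY2 by 1.10, the glucose transporter SLC2A3 by 1.5 and CITED4 by 1.45. MMP1, MMP10, SPRY2 and CITED4 started lower in untreated S276A cells, at −1.71, −2.15, −1.72 and −1.6 against wild type. After EGF they stood at −0.298, −0.667, −0.623 and −0.148, so they did not exceed the wild-type level. MMP3, DUSP5 and SLC2A3 did, by 0.634, 0.985 and 1.64. TNFSF10 changed by −2.78 in wild type and −0.43 in S276A, a difference of 2.35 ± 0.47 (0.0458), but its mean untreated S276A level of 4.48 already lay below the background limit. In total 37 probes passed, 21 genes higher and 6 lower in S276A. Of EGFR-ERK genes 2 of 38 responded more (12 over the list alone, median 0.34, camera adjusted p = 3.86e-05, 0.0412 estimated). NF-κB targets shifted downward in camera (2 of 37, 3 up and 5 down over the list alone, median −0.099, adjusted p = 0.0476), with adjusted p = 0.35 with an estimated correlation. Their medians at the ends of the chip were 0 and 0.0026, and the 2 genes past the threshold were CXCL8 and TNFAIP3, so a weaker response of the whole set is not shown. Mitotic (0.0265) and cholesterol lists (0.0123) shifted downward, with 0 of 35 and 0 of 19 genes past limma adjustment over all genes, 4 and 4 lower at unadjusted p below 0.05, and 0 and 2 lower over the list alone. These gave adjusted p = 0.668 and 0.271 with an estimated correlation. Proteases (4 of 21, 5 up and 3 down over the list alone, 0.0441) and TGF-β targets (1 of 19, 4 up and 1 down over the list alone, 0.0144) responded more. With an estimated correlation these gave adjusted p = 0.541 and 0.0959. By level the protease list was lower in S276A, with median genotype effects of −0.83 untreated and −0.539 under EGF. Each end of the chip held 1 array of every group, so no test within an end is possible. The EGFR-ERK median was 0.41 at one end and 0.39 at the other, and with chip end as a block 82 probes passed, 43 higher and 39 lower. Without an intensity trend 0 probes passed in limma, with 2385 at unadjusted p below 0.05, against 2433 with the trend. Leaving out 1 array at a time gave 4 to 38. The balance turned to 14 higher and 24 lower without a probe filter, where 5 of the 37 probes passed again, and to 15 and 23 without WT_EGF replicate 1, where 18 did.

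For the IL-1β response, interferon-stimulated genes responded less in S276A. IFIT2, an antiviral gene, changed by 3.41 in wild type and −0.61 in S276A, a fitted difference of −4.02 ± 0.49 (adjusted p = 0.000294). CXCL10 differed by −3.35 ± 0.40 (0.000294), LTB by −4.17 ± 0.41 (1.92e-05), the monocyte attractant CCL2 by −2.37 ± 0.43 (0.0251) and the guanylate-binding GBP2 by −1.90 ± 0.30 (0.00591). IFIT2, LTB and CCL2 lay below the background limit in untreated cells of both genotypes and in S276A after IL-1β, so their fitted differences are not exact. Nor is that of CXCL10, with 1 of 2 arrays above the limit in untreated wild type and in S276A after IL-1β. After IL-1β they stood at least 12.8-fold, 45.3-fold and 5.87-fold lower in S276A than in wild type. Other genes gained more in S276A, including CLDN1 by 2.47 ± 0.32 (0.00039), IRF1 by 1.65 ± 0.21 (0.000425), the prostaglandin enzyme PTGS2 by 1.64 ± 0.22 (0.000595), DUSP1 by 1.34 and the kinase IRAK2 by 1.31. In untreated cells PTGS2 stood at 11.33 in wild type and 9.29 in S276A, and IRF1 at 7.74 and 6.74. In total 33 probes passed, 14 genes higher and 13 lower in S276A. Interferon-stimulated genes had 3 of 31 lower (8 over the list alone), a median of −0.38 and camera adjusted p = 5.63e-09 (0.0457 with an estimated correlation), with medians of −0.37 and −0.39 at the ends of the chip. EGFR-ERK genes responded more (4 of 38, 13 up and 1 down over the list alone, median 0.39, 2.91e-07, 0.0258 estimated), with 0.37 and 0.48 at the ends. NF-κB targets had 3 up and 3 down of 37 (9 and 7 over the list alone), a median of 0.092, a mean of −0.12 and a downward test (adjusted p = 0.893). EGF family ligands (0.00182), TGF-β targets (0.00328) and squamous genes (0.0292) responded more with the preset correlation, with adjusted p = 0.0737, 0.0683 and 0.213 with an estimated correlation. In these lists 0 genes passed in limma over all genes, and 2, 6 and 1 rose over the list alone. Without an intensity trend 7 probes passed, and with an offset of 64 there were 57, 26 higher and 31 lower. The balance was 14 higher and 19 lower without a probe filter, where 6 of the 33 probes passed again. Leaving out 1 array at a time gave 8 to 39.

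**Figure D2:**
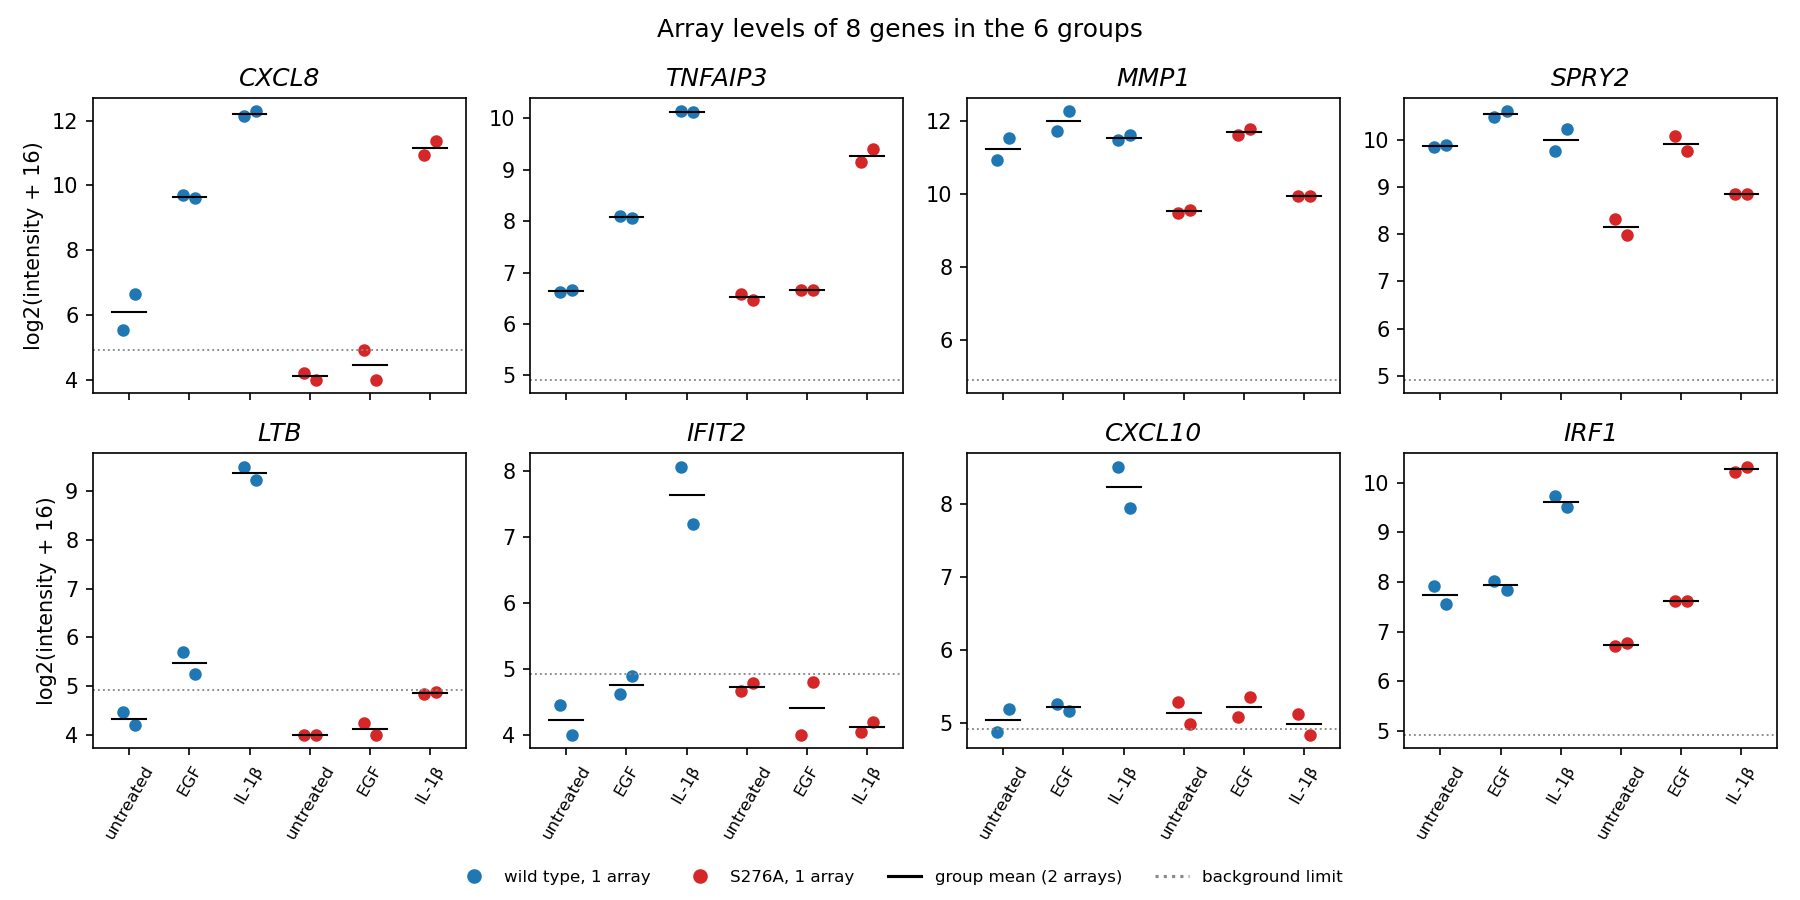
Log2 intensity (vertical) by treatment (horizontal) in wild type and S276A for 8 genes, 1 point per array, 2 arrays per group. The dotted line marks the background limit of 4.92.

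The 2 interactions share the 4 untreated arrays, so they are not independent. DUSP5 and HAS3 passed in both with larger responses in S276A, and MMP3 passed in opposite directions. By probe, 3 passed in the same direction, where independent lists would give 0.0167 up and 0.00456 down. The covariance across probes was 0.0801 against 0.0815 simulated, and r was 0.424 against 0.5. With the untreated arrays split between the responses r was −0.0097 or 0.018. The correlation across probes is thus no more than the shared arrays alone give. After that split 0 probes passed in both, but only 1 and 7, or 6 and 4, passed in each interaction, too few to judge the overlap. Part or all of the overlap may come from the shared arrays.

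**Figure D3:**
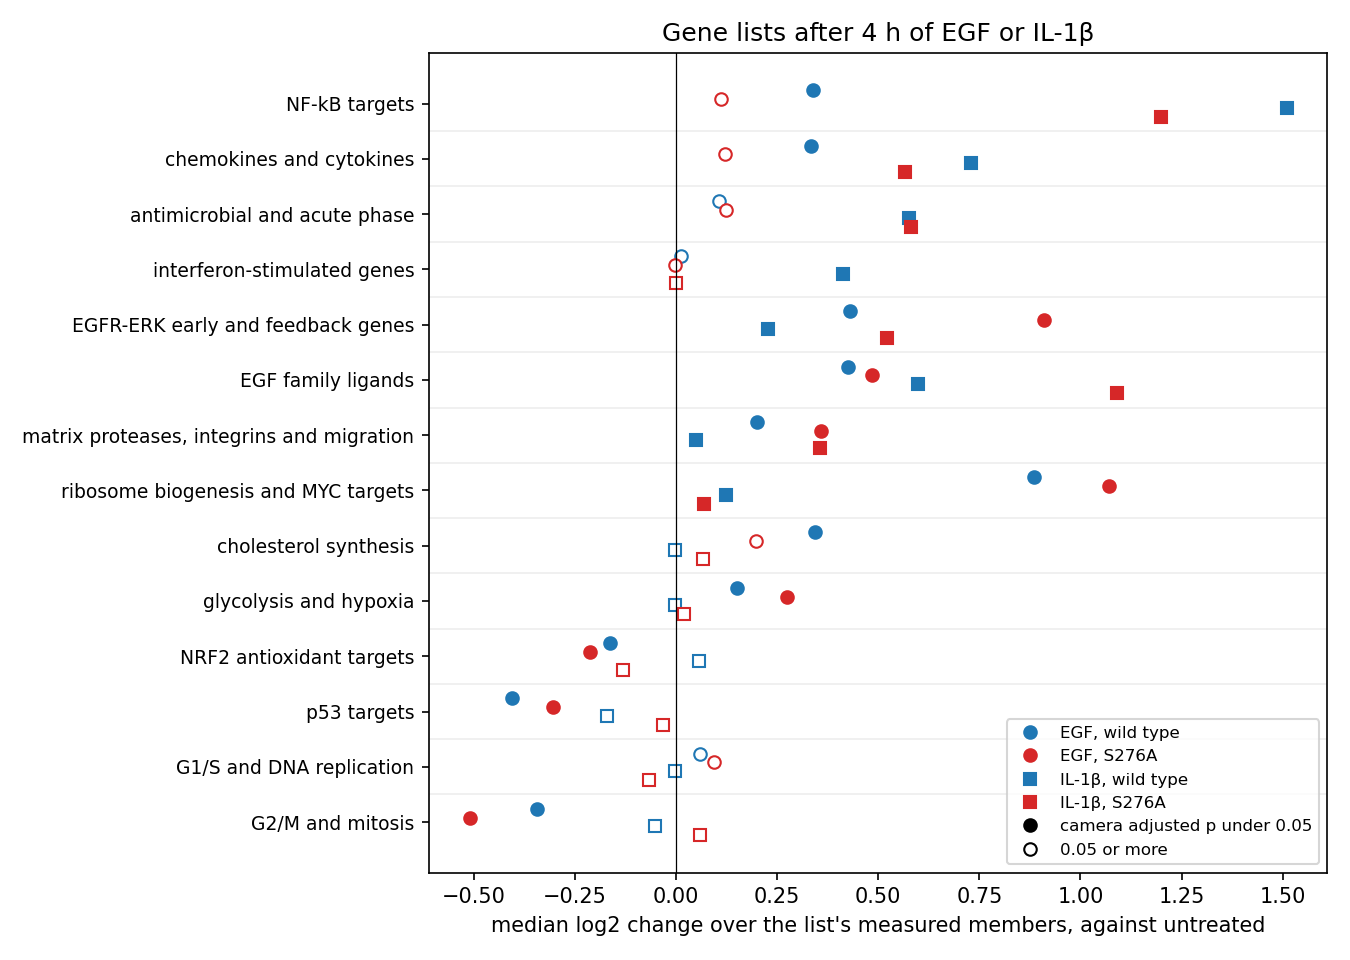
Median log2 change (horizontal) of 14 gene lists (vertical) after EGF or IL-1β in wild type and S276A, 1 point per list and response, filled where camera adjusted p is under 0.05. NF-κB targets rose by a median of 1.51 with IL-1β in wild type.

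In untreated cells S276A had lower levels of cell-cycle and protease genes, and single genes differed by more. The small proteoglycan BGN was higher by 4.35 ± 0.16 (adjusted p = 2.41e-14), the receptor NOTCH3 by 3.58 ± 0.28 (at least 18.1-fold) and the collagen-binding DCN by 2.67 ± 0.18. The homeobox gene IRX4 was lower by 4.43 ± 0.23 (at least 23.1-fold, 2.31e-11), the histone variant MACROH2A2 by 3.39 ± 0.21, the adhesion gene CDH2 by 2.42 ± 0.14. TNFSF10 differed by −3.21 ± 0.33, with 1 of 2 S276A arrays above the background limit, so that value is not exact. CXCL8 lay below the limit in S276A and was lower by at least 3.56-fold, PTGS2 by 2.05 ± 0.16, MMP10 by 2.15 ± 0.20, and the mitotic kinase BUB1 and replication factor CDC45 by 1.71 ± 0.20 and 1.80 ± 0.17. In total 2206 probes passed, 580 genes higher and 855 lower. Of mitotic genes 35 of 35 were lower (median −1.26, camera adjusted p = 2.73e-32), and of proteases and integrins 14 of 21 (18 over the list alone, 5.6e-14), with adjusted p = 0.0737 with an estimated correlation for each. G1/S genes (18 of 33 lower, 22 over the list alone, 3.04e-16, 0.0391 estimated) and EGFR-ERK genes (16 lower and 1 higher of 38, 20 and 2 over the list alone, 1.87e-06, 0.0285 estimated) were lower and held. NRF2 targets were higher (9 up and 1 down of 20, 12 and 1 over the list alone, 3.29e-06), with AKR1C3 at 1.54, and adjusted p = 0.0711 with an estimated correlation. At the ends of the chip the mitotic median was −1.06 and −1.51. The probe count was 974 without an intensity trend and 864 when only these 4 arrays were fitted.

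Other lists also differed in untreated cells by the preset correlation alone. NF-κB targets (6 of 37 lower, adjusted p = 0.0166), TGF-β targets (6 lower and 1 higher of 19, 0.00326), cholesterol genes (5 lower and 1 higher of 19, 0.00377), unfolded protein genes (9 lower and 1 higher of 22, 0.0299) and EGF family ligands (2 of 5 lower, 0.0292) were lower. Ribosome biogenesis (5 of 26 higher, 0.00233) and antimicrobial genes (3 higher and 1 lower of 14, 0.0347) were higher. With an estimated correlation these gave adjusted p = 0.269, 0.0683, 0.225, 0.148, 0.155, 0.269 and 0.148. Among cell-type markers squamous genes gave 0.0989, basal 0.794, luminal 0.227, fibroblast 0.832 with 4 higher and 6 lower of 21, immune 0.39 and endothelial 0.751. Of the immune and endothelial markers 0 passed in limma, with 2 and 0 at unadjusted p below 0.05. Over all 225 list tests 89 passed with the preset correlation and 28 of those with an estimated one. Median, mean and test direction differed in sign in 29 tests, and these all missed the threshold.

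**Figure D4:**
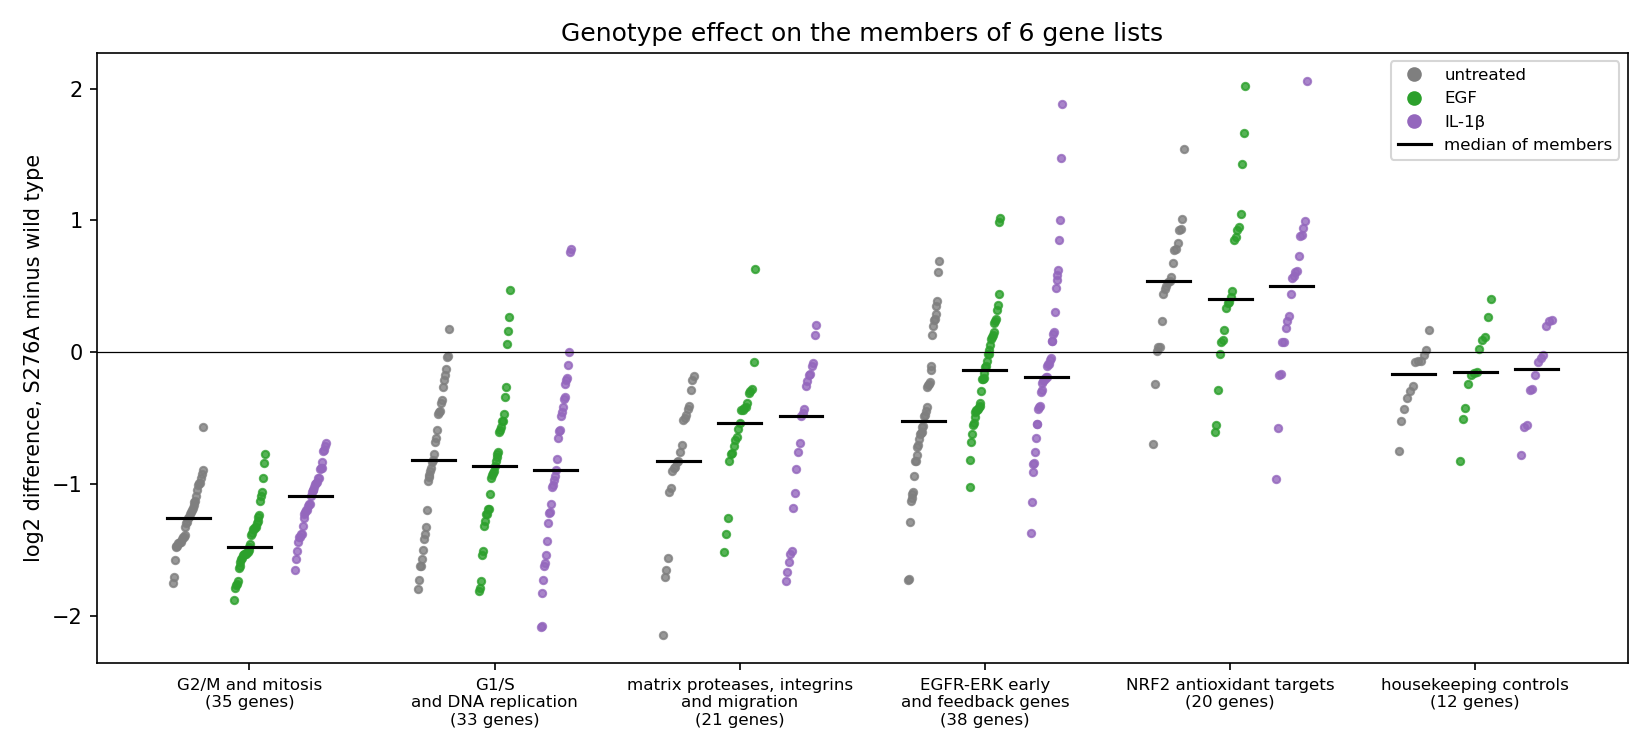
Log2 difference of S276A from wild type (vertical) for the members of 6 gene lists (horizontal), 1 point per gene in untreated, EGF-treated and IL-1β-treated cells, 2 arrays per group. Lines mark medians, which for the mitotic list lay at −1.26, −1.48 and −1.09.

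Averaged over the 3 treatments the genotype differences were the most numerous, 6064 probes (limma), with 1751 genes higher and 2004 lower in S276A. This comparison sets more arrays against each other than a single response does, so its standard errors are smaller and smaller differences pass. Of these genes 146 were higher and 291 lower by at least 2-fold. EGF moved more genes that far, 314 up and 320 down in wild type and 510 and 373 in S276A. In the genotype average BGN was higher in S276A by 4.55 ± 0.091 (adjusted p = 4.74e-20) and the sulfatase SULF1 by 3.42. IRX4 was lower by 4.19 ± 0.13 (3.99e-16). TNFAIP3 was lower by 0.80, and CXCL8 and LTB gave fitted values of −2.75 ± 0.16 and −2.06, which are not exact because several group levels lay below the background limit. Mitotic genes were lower, 35 of 35 (median −1.30, camera adjusted p = 5.64e-31), with adjusted p = 0.0742 with an estimated correlation. G1/S genes were lower, 25 of 33 (27 over the list alone, 6.8e-17), and held (0.0391 estimated). NF-κB targets were lower (13 down and 1 up of 37, 19 and 2 over the list alone, median −0.30, 0.00013), with adjusted p = 0.118 with an estimated correlation. This average includes the treated arrays, so genes whose response differs also enter it. In comparisons added after the data had been seen, 3126 probes differed between genotypes under EGF and 2577 under IL-1β. Under IL-1β the interferon-stimulated list had a median genotype effect of −0.51 with 8 of 31 genes lower, against 0.0019 in untreated cells.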

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

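The tests on the strength of the IL-1β response, IRF1, untreated EGFR-ERK levels, fibroblast transcripts and clone were chosen only after the results had been seen. The genes and lists below stood out because the responses of the genotypes differed, genes in a direct limma test and lists in camera, so each marks a difference between groups. The mitotic genes are weighed beside them as a genotype effect averaged over treatments, not a difference in response.

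Interferon-stimulated genes gained less from IL-1β in S276A, with a median difference of −0.38 over the list, IFIT2 at −4.02, CXCL10 at −3.35 and UBE2L6 at −1.03, although UBE2L6 started 1.25 higher in untreated S276A cells. A stray IL-1β array is excluded as the sole source, because without any 1 of the 4 such arrays the median stayed at or below −0.313, although the group left with 1 array is assumed to vary like the others. Less IRF1 transcript at 4 h is excluded, as IRF1 stood 0.651 higher in S276A after IL-1β. In untreated cells it was lower in S276A, at 6.74 against 7.74 in wild type. Times between were not measured, so less IRF1 early in the response stays open. Of NF-κB targets 3 gained more in S276A, namely PTGS2, IRF1 and IER3, and 3 gained less. Those that gained more started lower in untreated S276A cells, at −2.05, −1 and −1.73. After IL-1β PTGS2 and IER3 stood at −0.405 and −0.761 against wild type. Of these 3 only IRF1, higher in S276A after IL-1β, argues against a weaker IL-1β response of every such gene. By level after IL-1β, 12 of 37 NF-κB targets were lower and 4 higher in S276A (median −0.241). A weaker response in part of them stays open, as the list had a median difference of 0.092 and a mean of −0.12. Whether the serine change or clone history sets this difference stays open too, as the labels tell apart 1 edited line, and estimating the correlation between genes left the list at adjusted p = 0.0457.

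EGFR-ERK genes gained more in S276A with each stimulus, by a median of 0.34 for EGF and 0.39 for IL-1β. A stray untreated array is excluded as the sole source, because without any 1 of the 4 untreated arrays the lower median was still 0.298. A lower starting level in S276A fits these values. The list stood at −0.521 in untreated S276A cells and at −0.14 and −0.19 under EGF and IL-1β. By median the genotypes thus differ mainly before treatment. Of the members past the threshold, SPRY2 (−1.72), EPHA2 (−1.11) and IER3 (−1.73) also started lower in S276A. DUSP5 (−0.265, limma adjusted p = 0.414) and DUSP1 (0.128, 0.759) did not pass untreated. They stood 0.848 and 1.47 higher in S276A after IL-1β, which a low start does not account for. For the list median the larger gain may reflect a low untreated state and not a stronger signal. Whether the edit or the clone sets that state stays open.

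Mitotic genes were lower in S276A in every treatment, with a median of −1.30 averaged over treatments, as part of 6064 probes, though the list gave adjusted p = 0.0742 with an estimated correlation. Of 100 splits of the arrays, with treatment kept as a term, only the real one reached 5679 probes, and the highest of the others gave 1291. The other splits leave the difference between the lines in the residual spread, so low counts there (median 0) are built in. The ranking shows that the arrays differ by line, and it cannot exclude a chance difference between lines or cultures. Fibroblasts in the S276A cultures, which could bring BGN and DCN, would be likely to raise their abundant transcripts alike. Of 6 such transcripts, picked after the result, 2 fell and 0 rose past the threshold, with a median of −0.231. COL3A1 lay below the background limit in untreated S276A cells, and the whole list of 21 markers had a median of −0.071 against 2.64 for DCN. These values argue against fibroblasts as the source, and a small share of them is not excluded. Clone choice or culture history cannot be told from the edit, because the labels tell apart 1 edited line.

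For the EGF response 37 probes differed between genotypes. Higher in S276A were TNFSF10 at 2.35, JMY at 1.56, SLC2A3 at 1.5, SLITRK6 and MMP10 at 1.49 each, CITED4 at 1.45, SH3YL1 at 1.43, MMP1 at 1.41, MMP3 at 1.40, DUSP5 at 1.25, SPRY2 at 1.10, CCN2 at 1.01 and TWIST1 at 0.95. Lower were CXCL8 at −3.21, TMEM200A at −2.07, TNFAIP3 at −1.31, FSTL3 and C21orf58 at −1.04 each and NAV2 at −0.96. As list medians, NF-κB targets stood at −0.099, mitotic genes at −0.195, cholesterol genes at −0.183, EGFR-ERK genes at 0.339, proteases at 0.135 and TGF-β targets at 0.341. With an estimated correlation the EGFR-ERK list alone stayed past the threshold, and the others in that order gave adjusted p = 0.35, 0.668, 0.271, 0.541 and 0.0959. In S276A the mean levels of CXCL8, TMEM200A and TNFSF10 lay below the background limit before and after EGF, so their values are not exact.

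For the IL-1β response 33 probes differed. Higher in S276A were CLDN1 at 2.47, IL24 at 1.94, SEMA3B at 1.69, HAS3 at 1.68, IRF1 at 1.65, PTGS2 at 1.64, EPHA2 at 1.60, GDF15 at 1.37, DUSP1 at 1.34, IRAK2 at 1.31, DUSP5 at 1.11 and IER3 at 0.97. Lower were LTB at −4.17, IFIT2 at −4.02, CXCL10 at −3.35, CCL2 at −2.37, MRGPRX4 at −2.35, GBP2 at −1.90, ZNF215 at −1.72, PARP8 at −1.53, SRGN at −1.30, CPNE8 at −1.06, UBE2L6 at −1.03 and MMP3 at −0.91. As list medians, interferon-stimulated genes stood at −0.384, EGFR-ERK genes at 0.391, EGF family ligands at 0.492, TGF-β targets at 0.208 and squamous genes at 0.197. The last 3 lists lost the threshold with an estimated correlation (adjusted p = 0.0737, 0.0683 and 0.213). In CXCL10 some arrays lay below the background limit. LTB, IFIT2, CCL2 and MRGPRX4 lay below it in S276A before and after IL-1β, and IL24 in untreated S276A cells, so the values of these 6 genes are not exact.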

How the results depend on the processing

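No test described in this part was chosen after the result was seen. Adding a replicate block moved no count by more than 1.5-fold (for example 3039 probes for EGF in wild type). No named gene past its threshold turned direction in a refit of its own probe, and no list did in the settings run for all lists. Those settings include neither array weights nor the removal of single arrays. Single arrays were removed only for the interferon-stimulated and EGFR-ERK lists, as described above. The balance of the interactions did turn. Normalising again or centring moved counts by a few probes (EGF in wild type 3014 and 3012, EGF in S276A 3791 and 3785), since the columns already coincide. camera does not use the intensity trend, so that setting is void for lists. Under the filter at the 75th percentile the endothelial list gave no value in 9 comparisons.

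Without a probe filter 289 probes passed for IL-1β in wild type, 259 for IL-1β in S276A and 1413 for genotype in untreated cells, and the overlap of EGF and IL-1β in wild type was 144. More probes are then tested and adjusted for. The EGF interaction gave 38, 14 higher and 24 lower in S276A, 5 of them shared with the 37, which had 27 higher and 10 lower. At unadjusted p below 0.05 in limma it had 3650 probes, against 2433 with the filter, and why its calls changed was not tested. Without an intensity trend EGF gave 1772 in wild type and 2474 in S276A, IL-1β 178 and 161, and the interactions 0 for EGF (limma, 2385 at unadjusted p below 0.05) and 7 for IL-1β. The same setting gave 974 for genotype untreated, 1179 for IL-1β against EGF and an overlap of 79. With only the groups compared, EGF gave 1030 and 1796, IL-1β 28 and 80, the EGF interaction 5, genotype untreated 864, IL-1β against EGF 347 and the overlap 9, as fewer arrays estimate the spread. The correlation between genotypes became 0.81 for EGF and 0.585 for IL-1β under the 75th percentile filter, 0.215 and 0.0747 with an offset of 1, and 0.731 and 0.455 with an offset of 64, because near-background probes weigh more or less. The IL-1β interaction gave 57 with an offset of 64 and 59 with array weights, and the EGF interaction 82 with chip end as a block, and for these the cause was not tested.

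Leaving out 1 array at a time, the lone array of a group is assumed to vary like the other groups. EGF in wild type ranged from 1812 to 3078, with 1812 and 1843 without WT_UT replicate 1 and 2. IL-1β in wild type ranged from 227 to 517, with 248 and 266 without WT_UT replicate 1 and 2, and 227 without WT_IL1 replicate 2. EGF in S276A ranged from 2316 to 3925, with 2431 and 2316 without S276A_UT replicate 1 and 2. IL-1β in S276A ranged from 190 to 440, with 238 and 200 without S276A_UT replicate 1 and 2, and 262 and 190 without S276A_IL1 replicate 1 and 2. The EGF interaction ranged from 4 to 38, with 38 (15 higher and 23 lower) without WT_EGF replicate 1, 21 and 8 without WT_UT replicate 1 and 2, 19 without WT_EGF replicate 2, 8 and 12 without S276A_UT replicate 1 and 2, 9 and 4 without S276A_EGF replicate 1 and 2, and 20 and 19 without S276A_IL1 replicate 1 and 2. The IL-1β interaction ranged from 8 to 39, with 14 without either WT_UT replicate or WT_IL1 replicate 1, 10 and 11 without S276A_UT replicate 1 and 2, and 18 and 8 without S276A_IL1 replicate 1 and 2. Genotype untreated ranged from 1066 to 2330, with 1430 and 1066 without WT_UT replicate 1 and 2, and 1136 and 1244 without S276A_UT replicate 1 and 2. IL-1β against EGF ranged from 1291 to 2361, with 1335 without WT_EGF replicate 2 and 1291 without WT_IL1 replicate 1. Genotype averaged ranged from 5028 to 5982.

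Among 686 named gene results, 152 fell short of the threshold without a probe filter, 155 without an intensity trend, 211 with only the groups compared, 57 with an offset of 1, 12 with an offset of 64, 8 with array weights, 6 with the 75th percentile filter and 4 with the replicate block. Leaving out 1 array made 30 to 84 fall short, the most without WT_UT replicate 2. With chip end as a block 3 gained the threshold. Of other probes for named genes 128 fell short, 144 kept their call, 5 gained the threshold and 25 differed in sign, without passing in both. Of 225 list results 61 fell short with an estimated correlation and 164 kept their side, and with only the groups compared 9 fell short and 1 gained. Under the 75th percentile filter 11 lists fell short and 5 gained, and without a filter 6 and 3. Lists that missed the threshold changed direction in 15 cases under the 75th percentile filter, 10 without a filter, 7 with only the groups compared, 6 with an offset of 1, 3 with the replicate block and 2 with chip end as a block. Signal limits the genes near background, since 42.5% of probes lay above the limit in each array.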

Other observations

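The test of FOXO-activated genes was chosen after the falls of FBXO32, BCL6 and PIK3IP1 had been seen, and that of aryl hydrocarbon receptor targets after those of CYP1A1 and CYP1B1. EGF also lowered genes in wild-type cells that are not described above, picked here from the FOXO list. TXNIP, which limits glucose uptake, fell by 2.15 ± 0.14, the cell-cycle inhibitor genes CCNG2 and CDKN1B by 1.64 and 1.12, and the transcription factor gene KLF9 by 1.49. The stress regulator HBP1 fell by 1.75 and KLHL24 by 2.05. INSR, TRIM63, BCL2L11, RICTOR and MXI1 of the same list did not pass.

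The set test left out genes named before, genes of other lists and genes printed in earlier tables, among them PIK3IP1, TXNIP and CITED2. Of the remaining 21 genes 16 fell with EGF in wild type (17 over the list alone, median −1.09, camera adjusted p = 1.58e-12 over 10 tests, 0.00448 with an estimated correlation). In S276A 14 fell (16 over the list alone, median −0.771, adjusted p = 5.45e-08, 0.0086 estimated). An earlier run that still held those 3 genes, 24 in all, gave medians of −1.17 and −0.884. The genotype difference over the 21 genes had a median of 0.341 (adjusted p = 0.0187), but adjusted p = 0.101 with an estimated correlation, and 1 gene passed over the list alone. IL-1β shifted the set in wild type by a median of −0.258 with 1 gene past the threshold (0.00803), but adjusted p = 0.0977 with an estimated correlation. EGF may lower FOXO activity in both genotypes, a hypothesis that the median of −0.771 in S276A fits, though transcripts do not measure FOXO protein or its location.

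The 8 other aryl hydrocarbon receptor targets fell with EGF by a median of −0.379 in wild type, 3 of them past the threshold, with UGT1A6 at −1.98 and ALDH3A1 at −0.93 (camera adjusted p = 0.0127). In S276A the median was −0.295 with 2 past the threshold (0.0403). IL-1β gave a median of −0.321 in wild type (0.0273) and −0.077 in S276A (0.573), and its wild-type response shares the untreated arrays with that to EGF. The difference between the stimuli was not tested for this list. The prediction asked for camera p past its threshold in both genotypes, which the preset correlation met, but with an estimated correlation adjusted p = 0.101 and 0.126 for EGF and 0.113 for IL-1β. Lower activity of this receptor may be involved, and with so few genes the median of −0.295 cannot tell.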
